A study of Mus musculus with 4 samples.

How the data were processed

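Values in the deposited matrices are UMI counts per gene and barcode, as the authors deposited them and per the file headers, and every entry was a whole number. Per the submitters' processing notes, reads were processed with Cell Ranger 3.0 against mm10 and analysed with Seurat 4.0, while the matrix headers name Cell Ranger 6.0.0. Per the labels, cells were sorted for CD11c and MHC-II, pooled from 3 tumors per library, loaded for up to 10000 cells and sequenced at 50000 reads per cell. The deposited matrices were used as they are, without realignment. Of 32285 gene identifiers, 32235 were found in GENCODE M21 (GRCm38), which gave the coordinates. Of 350 list genes 348 were found in the files, and the 2 others were left out.

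Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs passed the filter, which were 8745, 15656, 1810 and 671 for Ad-Null, Ad-MEM40, Ad-mIFNB and Ad-COMBO. Doublets were called per library with Scrublet as in scanpy. The expected share was 0.8% per 1000 barcodes. Its automatic threshold was kept unless it marked more than 2 times that share or, in a library of over 5000 cells, under 0.5%, in which case the expected share of cells with the highest scores was removed. It marked 1459 cells of Ad-Null (16.7%), 3 of Ad-mIFNB and 3 of Ad-COMBO. In Ad-MEM40 it marked 0%, so 2278 cells (14.6%) were removed by the expected share. Barcodes that failed the filter or were called doublets were left out of all results but the vector genes over all barcodes.

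Counts were scaled to 10000 per cell and log-transformed for clustering. The 2000 most variable genes, without the response and state lists, gave 30 components, 15 neighbours and Leiden clusters at resolution 1 with 10 iterations and seed 1, fitted jointly over the 4 libraries without batch correction. A cluster took the name of the cell type with the most markers at least 2-fold above all other cells. It needed at least 3 such markers and a share of markers 1.5 times that of the next type. A cluster far shallower than its libraries also needed such a marker among its 10 leading genes of at least 50 CPM. These naming thresholds were set after the clusters were seen, whereas the marker lists were fixed before. Of 24 clusters, 6 stayed unnamed. Classes were compared with at least 50 cells in both libraries.

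UMIs were summed over the cells of a library or class and given as CPM. Log2 ratios had 5 CPM added to both sides. CPM intervals are exact Poisson intervals at 95%, shares have Clopper-Pearson intervals, and list medians have intervals from 2000 Poisson draws of each count. List members needed at least 20 UMIs over both sides, a median needed at least 3 members, and 10000 random lists matched on expression gave its percentile. Genes counted as higher or lower at 1.5-fold. A gene without UMIs was taken as under a limit of 3 UMIs.

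Genes named by rule had at least 50 CPM in 1 of the 2 libraries and at least 50 UMIs over both, and the 10 highest and 10 lowest ratios were taken in all kept cells and the 5 highest and 5 lowest in mature DC-like cells. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor segment, Xist, Y-linked and Gm or Rik genes were left out by rule. A gene met by this rule, and a test that used it, are not reported here. Other genes in the text are members of the fixed lists, leading genes of a cluster or genes met in the results flagged for a closer look. The genes left out by rule could still be leading genes of a cluster. Shares of cells with a UMI were computed for 18 genes after thinning each cell to 1000 UMIs, leaving out shallower cells. The 4 genes printed were picked after the values of the 18 were seen.

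The cell type marker lists were cDC1, cDC2, mature DC, pDC, monocyte, macrophage, neutrophil, mast cell or basophil, B cell, T or NK cell, melanoma, endothelial, fibroblast and erythroid. The response and state lists were type I interferon response, interferon gamma associated, CD40 and NF-kB targets, DC maturation and costimulation, MHC class I presentation, MHC class II presentation, chemokines, cytokines, inhibitory molecules, cell cycle, dissociation and heat stress, hypoxia and glycolysis, and phagocytosis and lysosome. The mast cell or basophil list had under 3 measured members and has no median, nor has the erythroid list in Ad-mIFNB or Ad-COMBO against Ad-Null. Of 20 maturation genes, 6 are mature DC markers, 1 is an NF-kB target and 3 are inhibitory molecules. Groups, filters, lists, the rule for named genes and 13 alternatives were set before the data were examined.

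Simulated data were Poisson draws of both libraries of a comparison from their pooled profile, each at its own depth, with 1.5-fold, 2-fold and 4-fold differences planted in 200 of the genes at 50 CPM or more. The step ran on 2938, 2910 and 2902 genes for Ad-MEM40, Ad-mIFNB and Ad-COMBO against Ad-Null in all kept cells, and on 2657, 2719 and 2654 in mature DC-like cells. In all kept cells, genes planted 1.5-fold higher came back with median log2 ratios of 0.53, 0.53 and 0.53 for Ad-MEM40, Ad-mIFNB and Ad-COMBO, 2-fold with 0.93, 0.95 and 0.92, and 4-fold with 1.92, 1.93 and 1.91. Genes planted lower came back at -0.59, -0.59 and -0.59, at -0.98, -0.97 and -0.99, and at -1.86, -1.85 and -1.84. Unchanged genes were at -0.036, -0.027 and -0.043. In mature DC-like cells the medians were 0.56, 0.54 and 0.53 for 1.5-fold, 0.95, 0.97 and 0.93 for 2-fold and 1.92, 1.93 and 1.91 for 4-fold higher, and -0.60, -0.60 and -0.56, -0.97, -0.97 and -1.00, and -1.83, -1.95 and -1.89 for lower. Unchanged genes there were at -0.028, -0.029 and -0.037. A list of 20 genes planted 2-fold higher had medians of 0.93, 0.94 and 0.93 in all kept cells at percentile 100. Unchanged lists had -0.033, -0.027 and -0.032, at percentiles 64.8, 50.9 and 85.5. Their intervals excluded 0 (-0.043 to -0.027, -0.036 to -0.010 and -0.059 to -0.012). The planted folds raised the summed profile, which was then rescaled to a fixed total. The true ratios of unchanged genes thus lie slightly below 0, so these intervals did not miss them for that reason. In mature DC-like cells the lists planted higher had 0.94, 0.97 and 0.93. The unchanged ones there had -0.033, -0.020 and -0.081, the last at percentile 5.45. Medians this close to 0 can thus arise in lists without a planted gene, because differences in other genes shift the scale.

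Alternatives changed the cell filter (at least 1000 genes and at most 5% mitochondrial UMIs, or at least 200 genes and at most 20%), doublet removal, scaling (TMM factors, or without mitochondrial and ribosomal protein genes), the pseudocount (1 CPM), the low-count filter, the weight of classes, depth (cells thinned to 1000 UMIs, or no thinning of shares), clustering resolution (0.5 and 2) and the clustering features. Another 3 were added after the data were seen. They left 241 genes that differed within cDC1-like cells out of the features, left out melanoma-like, T or NK cell-like and fibroblast-like clusters, or left out clusters of under 5000 median UMIs.

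Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, R 4.3.3 and edgeR 4.0.16. Batch correction, trajectories and ligand-receptor scores were not used here, and raw reads were not analysed here.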

Results

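CD11c+ MHC-II+ cells from B16-F10 tumors were profiled by single-cell RNA sequencing after injection of 1 of 4 adenoviruses into the tumor. The viruses were an empty control (Ad-Null), Ad-MEM40, whose treatment label reads ISF35 (a CD40 ligand chimera), Ad-mIFNB, which carries mouse interferon beta, and Ad-COMBO, the mixture of ISF35 and mIFNB. C57BL/6 mice had received 500000 tumor cells under the skin and were injected on day 12. Each library pooled cells of 3 tumors, and each treatment had 1 library, so there were no replicates and no comparison below carries a statistical test. The questions were what each virus did to the myeloid cells of the tumor, and whether the mixture differed from the single viruses.

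The libraries held 11308 (Ad-Null), 18185 (Ad-MEM40), 2076 (Ad-mIFNB) and 954 (Ad-COMBO) barcodes, of which 7286, 13378, 1807 and 668 were kept. Kept cells had a median of 14106, 8945.5, 13613 and 11416.5 UMIs. Expression is given as CPM, UMIs summed over cells and scaled to 1000000 per sum, and ratios are log2 values with 5 CPM added to both sides. Bracketed values are 95% intervals that cover counting error only, not differences between tumors or libraries. Those of expression, drawn on summed UMIs, also leave out differences between cells. Genes keep the symbols of the deposited files, with positions from GRCm38 and GENCODE M21.

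The genes carried by the vectors were examined first. Ifnb1 (chromosome 4, 88522025 to 88522774) lay at 0.614 CPM (0.501 to 0.746) over all barcodes of Ad-Null, 1.04 (0.902 to 1.20) in Ad-MEM40, 3.08 (2.48 to 3.79) in Ad-mIFNB and 2.65 (1.76 to 3.82) in Ad-COMBO. Among kept cells of Ad-COMBO it was 1.15 CPM (0.572 to 2.05), an interval that overlaps that of Ad-Null (0.475 to 0.768). The 90 UMIs of Ad-mIFNB lay in 16 cells, with up to 21 in a single cell, and 17 of the 28 UMIs of Ad-COMBO lay in 1 barcode called a doublet, so these intervals understate the spread. Cd40lg had 97 UMIs over all barcodes of Ad-MEM40 and 1, 0 and 1 in Ad-Null, Ad-mIFNB and Ad-COMBO, where 3 UMIs, the limit used here, correspond to 0.0181, 0.103 and 0.283 CPM. Of its 57 UMIs in kept Ad-MEM40 cells, 36 lay in 5 melanoma-like cells, 21 of them in a single cell. Ad-COMBO held 10584385 UMIs over all barcodes against 186975859 in Ad-MEM40, and 2 kept melanoma-like cells against 218. Few Cd40lg UMIs could thus appear in Ad-COMBO even at the level of Ad-MEM40. Cd40lg therefore did not show the ISF35 label of Ad-COMBO, but its near absence does not speak against that label. Reads at the 3' end may also miss a vector transcript or fail to tell it from the mouse gene.

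Clusters were named by marker genes into cDC1-like, cDC2-like, mature DC-like, pDC-like, macrophage-like, monocyte-like and rarer classes. Mature DC-like cells, which carry the Ccr7 program of dendritic cells that migrate to lymph nodes, made up 7.54% (6.94 to 8.17) of Ad-Null cells, 8.32% (7.86 to 8.80) of Ad-MEM40, 18.0% (16.3 to 19.9) of Ad-mIFNB and 28.1% (24.8 to 31.7) of Ad-COMBO. Ad-MEM40 lay below Ad-Null under the stricter cell filter (6.31% and 6.70%). cDC1-like cells, the cross-presenting dendritic cells, were 17.7%, 14.5%, 17.7% and 22.3% of the 4 libraries in the same order. Macrophage-like cells were 14.9%, 20.0%, 9.80% and 9.28%, or 28.5%, 39.7%, 17.6% and 18.0% at the coarser resolution of 0.5. At that resolution the class took in a cluster led by Retnla, Lyz1 and Fn1. It also took in one led by histone genes, with 3 of 12 macrophage markers high. pDC-like cells were 3.20%, 1.47%, 2.99% and 3.59%. These are shares of cells sorted for CD11c and MHC-II, so they do not count cells per tumor, and median depth differed between libraries.

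cDC2-like cells were 31.3%, 22.1%, 11.6% and 3.59%, and monocyte-like cells 7.34%, 6.45%, 2.49% and 0.898%. Monocyte-like shares kept no order under other settings, and cDC2-like shares of Ad-MEM40 and Ad-COMBO stayed below Ad-Null, while their size in the interferon beta libraries depended on where a cluster was placed. Unnamed cluster 6, led by Ifit3b, Ifit1bl1 and other interferon genes and carrying 3 monocyte and 3 cDC2 markers, held 0.714% and 0.284% of Ad-Null and Ad-MEM40 cells but 25.6% and 18.0% of Ad-mIFNB and Ad-COMBO cells. At a coarser clustering (resolution 0.5) most of it fell among cDC2-like cells, which then were 32.9%, 23.1%, 35.2% and 18.0% of the 4 libraries. With all variable genes as features most of it was monocyte-like, and that class was 33.6% of Ad-mIFNB. Other unnamed clusters were 8 (7.51%, 5.95%, 4.26% and 4.49%), 9 (1.72%, 8.16%, 3.76% and 6.44%), 11 (2.54%, 2.57%, 0.443% and 0%), 17 (3.87%, 3.48%, 2.27% and 1.65%) and 21 (0.549%, 4.64%, 0.111% and 1.05%). Cluster 9 had 11 of 12 macrophage markers high but also 4 erythroid ones, so the macrophage-like shares above leave out its cells. Melanoma-like cells were 0.878%, 1.63%, 0.553% and 0.299%, T or NK cell-like cells 0.165%, 0.292%, 0.387% and 0.299%, and fibroblast-like cells 0.0274%, 0.127%, 0% and 0%.

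**Figure D1:**
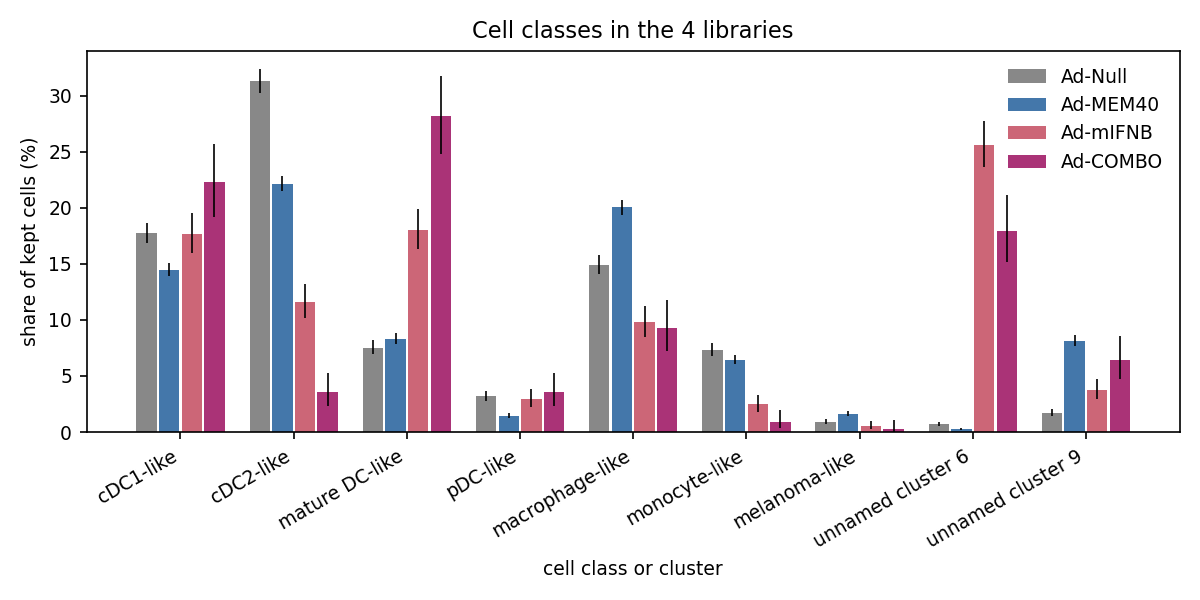
Share of kept cells in each class or unnamed cluster for the 4 libraries. Bars are percent of kept cells and lines 95% intervals for counting error; the mature DC-like bar is tallest in Ad-COMBO (28.1%) and the cluster 6 bar in Ad-mIFNB (25.6%).

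Ad-MEM40 cells carried more transcripts of macrophage markers than Ad-Null cells, and their interferon-stimulated genes were nearly level. Saa3, an acute-phase serum amyloid gene (chromosome 7, 46711998 to 46715700), was at 81.0 CPM (79.6 to 82.6) against 21.2 (20.3 to 22.0), the largest ratio among genes at 50 CPM or more (log2 1.72). The C-type lectin receptors Clec4d and Clec4e, which sense microbes and dying cells, were 1.36 and 1.26 higher. Ccl8, a chemokine for monocytes and T cells, was at 306 against 128 CPM (1.22). The heme-degrading enzymes Blvrb and Hmox1 were 1.11 and 1.04 higher, and the macrophage genes Folr2, a folate receptor, and Ms4a7 1.07 and 1.03. AW112010, an interferon-gamma-responsive RNA annotated as noncoding, was 1.06 higher, and Sparc, a matrix protein, 1.21.

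Cxcl1 and Cxcl2, which draw neutrophils, were at 0.90 and 0.78 in Ad-MEM40, beside Nos2 (nitric oxide synthase) at 1.21 and Gzma (a granzyme of cytotoxic lymphocytes) at 1.59. Cd70, the ligand of CD27, a costimulatory receptor on T cells, was 0.96 higher. On the lower side, Hist1h2ap, a replication-dependent histone gene, was at 254 CPM against 671 (-1.39), followed by Ccl17, a chemokine for CCR4-bearing T cells (-1.21), and Cd209a, a lectin of cDC2 and monocyte-derived cells (-0.97). The MHC-II loading subunit H2-DMb2 was at -0.90, Qpct (glutaminyl cyclase) at -0.86 and the snoRNA host gene Snhg6 at -0.84. The histone genes Hist1h4d, Hist1h2ae and Hist1h2ab were at -0.87, -0.83 and -0.78. Histone genes are near copies of each other, so reads may be split among them.

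By groups of genes, 8 of 12 macrophage markers were at least 1.5-fold higher in Ad-MEM40 than in Ad-Null (median 0.67), led by Ms4a7, Apoe (lipid transport) at 0.93 and the complement gene C1qb at 0.79. Of 18 interferon gamma associated genes 4 were higher (median 0.42), all guanylate-binding proteins, with Gbp2 at 0.70. Of 19 chemokines 8 were higher and 1 was lower (0.44), and 4 of 18 phagocytosis and lysosome genes were higher (0.36). None of 28 type I interferon genes reached 1.5-fold (0.13), nor any of 22 CD40 and NF-kB targets (0.28, or 0.18 with classes weighted equally). Of 20 DC maturation and costimulation genes 3 were higher (0.30), Cd70, Fscn1 (the actin bundler fascin) and Ccl22, and the median was 0.16 under the stricter cell filter and 0.46 with a pseudocount of 1 CPM. MHC class I and class II medians were 0.04 and -0.20, and the class II value turned to 0.032 when classes were weighted equally.

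Smaller shifts in Ad-MEM40 concerned cytokines (4 of 20 higher, 0.19), inhibitory molecules (2 of 18 higher, 0.16), stress genes (0.15), hypoxia genes (0.13) and cell cycle genes (0.01). Transcripts of other cells moved too. Fibroblast markers were at 1.21 (5 of 7 higher), melanoma markers at 0.62 (5 of 9 higher) and erythroid markers at 0.51, whereas pDC markers were at -0.53 (5 of 10 lower), cDC1 markers at -0.27 and cDC2 markers at -0.23. Mature DC markers were at 0.38, monocyte markers at 0.04, neutrophil markers at 0.07, T or NK cell markers at 0.06, endothelial markers at 0.13 and B cell markers at 0.00. With equal class weights the melanoma median turned to -0.084, the cDC2 median to 0.043 and the hypoxia median to -0.11.

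Ad-mIFNB cells carried far more interferon-stimulated transcripts than Ad-Null cells, while Retnla and 8 of 16 cell cycle genes were lower. Ifit3b, an antiviral RNA-binding protein of the Ifit family (chromosome 19, 34607970 to 34613401), was at 183 CPM (178 to 188) against 11.9 (11.3 to 12.6), a log2 ratio of 3.47. Its relatives Ifit1bl1, Ifit1, Ifit3 and Ifit2 were at 3.38, 3.19, 3.06 and 2.62, and near copies among them may share reads. Rsad2, the antiviral enzyme viperin, was the highest of these in level, at 855 CPM against 101 (3.02). Ly6c2, a surface antigen of inflammatory monocytes that interferon also induces, was at 727 against 105 CPM (2.74).

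Less familiar genes were among the highest in Ad-mIFNB as well. Lipg, an endothelial-type lipase, was at 2.93, Sct, the hormone secretin, at 53.2 CPM against 3.03 (2.86), and Apod, a lipocalin, at 2.68. Ccl5, a chemokine for T cells, was 2.29 higher, and Cxcl10, a ligand of CXCR3, 1.21, but Cxcl9, which shares that receptor, was at -1.33. Kdr, a VEGF receptor, was at 1.86 and the lymphotoxin gene Lta at 1.37. The lowest was Retnla, a marker of alternatively activated macrophages (chromosome 16, 48842551 to 48844461), at 13.6 CPM against 235 (-3.69). F13a1, the transglutaminase of monocytes and macrophages, was at -1.94, Lyz1, a lysozyme, at -1.72, and Ptgds, prostaglandin D synthase, at -1.34. Lyz1 turned to 0.87 with equal class weights. That weighting left out unnamed cluster 11, which was led by Retnla, Lyz1 and Fn1 and held 2.54% of Ad-Null and 0.443% of Ad-mIFNB cells.

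Among the lowest genes of Ad-mIFNB were replication-dependent histones, with Hist1h2ap at 81.7 CPM against 671 (-2.96), Hist1h2ae at -1.88, Hist1h3c at -1.58, Hist1h2ab at -1.42 and Hist1h1b at -1.38. The 8 cell cycle genes that were at least 1.5-fold lower (list median -0.58) included the mitotic kinetochore protein Cenpf (-1.24), the topoisomerase Top2a (-1.02) and Mki67 (-0.89), whereas Pcna, the replication clamp, was level (0.07).

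All 28 measured type I interferon genes were at least 1.5-fold higher in Ad-mIFNB (median 1.66, above every one of 10000 random lists of matched expression). Of 18 interferon gamma associated genes 12 were higher and 1 was lower (0.69), with the immunity-related GTPase Irgm1 at 1.56. MHC class I genes had a median of 0.45 with 7 of 19 higher, among them H2-Q7 (1.41), H2-T23 (1.08) and H2-K1 (0.89), or 0.22 with classes weighted equally, while class II genes stayed near level (0.08). Of 20 DC maturation genes 9 were higher (0.55), led by Ccr7 (1.08), Fscn1 (1.07) and the cytokine Il15 (0.98), and of 22 NF-kB targets 7 were higher and 1 was lower (0.39). With 5 classes weighted equally the maturation median was 0.023 and the NF-kB median 0.11. This weighting changes the share of every class and leaves out monocyte-like cells and the unnamed clusters, cluster 6 among them.

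Chemokines split in Ad-mIFNB, with 4 of 19 higher and 5 lower (median -0.29), and 8 of 20 cytokines were higher (0.30), with Il1b, the inflammasome cytokine, lower (-0.82). Stress genes were at 0.22, hypoxia genes at -0.20 (0.067 with equal class weights), phagocytosis genes at -0.02 and inhibitory molecules at -0.03, although Socs1, a brake on cytokine signaling, was 1.24 higher. Markers of other cells were lower, with fibroblast markers at -1.06, melanoma markers at -0.61 and monocyte markers at -0.41. Macrophage markers were at -0.17, cDC1 markers at 0.08, cDC2 markers at -0.03, pDC markers at 0.05, neutrophil markers at 0.20, T or NK cell markers at 0.11, B cell markers at 0.05 and endothelial markers at 0.17. Mature DC markers were at 0.62 and turned to -0.15 with equal class weights.

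Summed over all kept cells, Ad-COMBO had a strong interferon response and higher costimulatory and NF-kB genes than Ad-Null. Of 16 cell cycle genes, 10 were lower. Ifit1bl1 was at 166 CPM (158 to 174) against 11.8 (11.1 to 12.4), a log2 ratio of 3.35, followed by Rsad2 (3.31), Ifit3b (3.24), Ifit1 (3.02), Ifit3 (2.70), Ifit2 (2.70) and Oasl1, an interferon-induced regulator of translation (2.57). Sct was at 3.01, Saa3 at 185 against 21.2 CPM (2.86) and Apod at 2.57. Cd70 was 2.12 higher, Cd200, an inhibitory ligand, 2.03, and Il15 with its receptor chain Il15ra 1.77 and 1.92. Il12b and Il27, subunits of T cell-priming cytokines, were both at 1.91. Ccl5 was at 2.56 and Cxcl10 at 1.75. Cd8b1, a CD8 coreceptor chain and here a leading gene of pDC-like cells, was at 1.38.

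On the lower side of Ad-COMBO, Retnla had 9 UMIs, or 0.937 CPM (0.428 to 1.78) against 235, a ratio of -5.34. Cd209a was at -3.02, Hist1h2ap at -2.94, Hist1h2ae at -2.23, F13a1 at -2.16, Lyz1 at -2.13 and Hist1h1b at -1.82. Dct, a melanin enzyme of the tumor cells, was at -2.04, and Ccr2, the receptor that brings monocytes into tissue, at -2.02. Fn1, the matrix protein fibronectin, was at -1.77 and turned to 1.31 with equal class weights. That weighting kept only cDC1-like, macrophage-like and mature DC-like cells. It left out monocyte-like cells and unnamed cluster 11, which was led by Retnla, Lyz1 and Fn1 and held 2.54% of Ad-Null and 0% of Ad-COMBO cells.

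All 28 type I interferon genes were at least 1.5-fold higher in Ad-COMBO (median 1.71), and 14 of 18 interferon gamma associated genes were higher (1.25). DC maturation genes had a median of 1.43 with 18 of 20 higher, led by Fscn1 (2.15), Cd70 and the calcium channel subunit Cacnb3 (2.07), and the value was 0.71 with 3 classes weighted equally. Of 22 NF-kB targets 16 were higher (0.81), with Tnf at 1.53, the adaptor Traf1 at 1.38 and the adhesion molecule Icam1 at 1.12. MHC class I genes had a median of 0.67 with 11 of 19 higher (0.44 with equal class weights), and class II genes a median of -0.13. Of 20 cytokines 10 were higher (0.63), of 18 inhibitory molecules 8 were higher and 2 lower (0.49), and of 19 chemokines 8 were higher and 4 lower (0.32).

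The cell cycle median of Ad-COMBO was -0.67, and 4 of 16 hypoxia genes were lower (-0.46), while 6 of 16 stress genes were higher (0.42) and phagocytosis genes were at 0.19 (-0.011 in cells thinned to 1000 UMIs). Mature DC markers, 6 of which belong to the maturation list, were at 1.42 and cDC1 markers at 0.66, against -0.43 for cDC2 markers (6 of 12 lower) and -0.35 for monocyte markers (4 of 9 lower). Macrophage markers were at 0.20 (-0.31 in thinned cells), pDC markers at 0.39, T or NK cell markers at 0.31, neutrophil markers at 0.17, endothelial markers at 0.17 and B cell markers at 0.03. Melanoma markers were at -0.85 and fibroblast markers at -0.77.

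**Figure D2:**
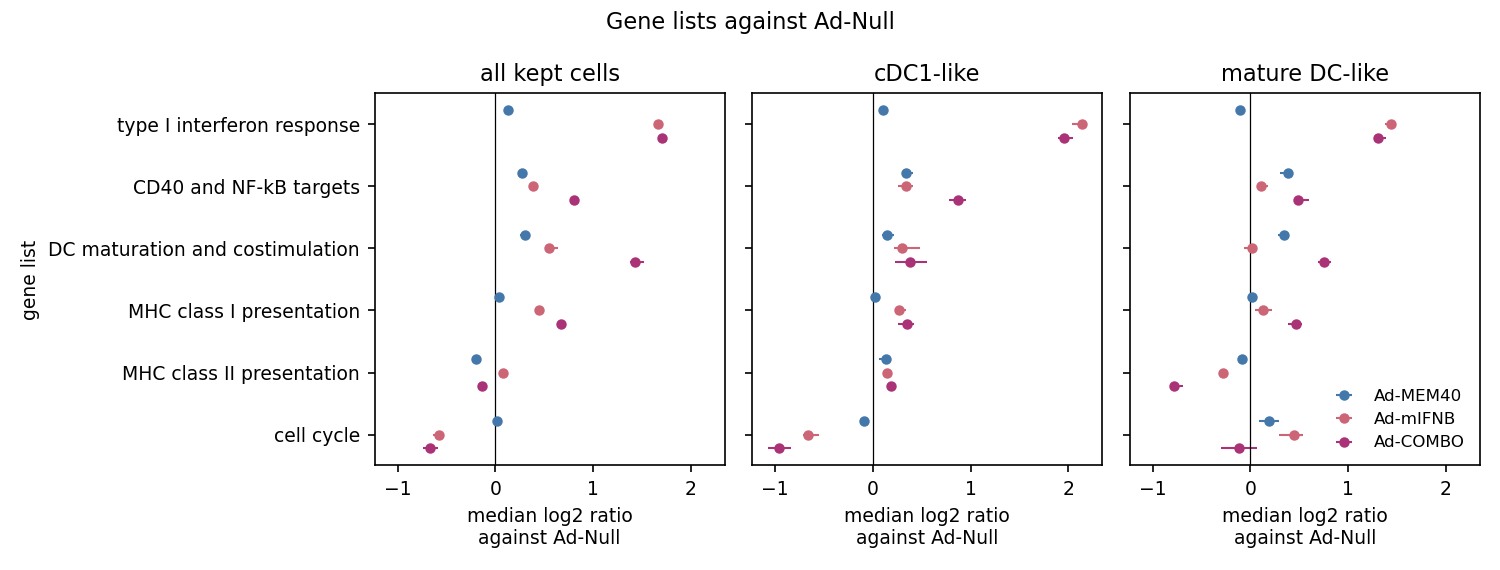
Median log2 ratio of 6 gene lists against Ad-Null in all kept cells, cDC1-like cells and mature DC-like cells. Points are list medians on the log2 scale and lines 95% intervals for counting error; interferon genes are high in Ad-mIFNB and Ad-COMBO (1.66 and 1.71 in all kept cells), maturation genes highest in Ad-COMBO (1.43).

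Set beside the single viruses, Ad-COMBO resembled Ad-mIFNB in interferon genes and lay above both in maturation genes. Type I interferon genes differed from Ad-mIFNB by a median of 0.09, which turned to -0.051 with equal class weights, and from Ad-MEM40 by 1.55, with 27 of 28 higher. Maturation genes were higher than in Ad-MEM40 by 1.15 (18 of 20) and than in Ad-mIFNB by 0.72 (13 of 20). NF-kB targets were higher by 0.53 and 0.43, and MHC class I genes by 0.63 and 0.20. With equal class weights the differences from Ad-MEM40 shrank to 0.40 (maturation), 0.32 (NF-kB) and 0.38 (MHC class I). Against the sum of the log2 ratios of the single viruses, Ad-COMBO differed by a median of 0.40 (0.38 to 0.48) in maturation genes, 0.26 (0.22 to 0.29) in NF-kB targets, 0.15 (0.097 to 0.18) in MHC class I genes and -0.084 (-0.11 to -0.054) in type I interferon genes. The difference in maturation genes was 0.62 under the stricter cell filter, and that in MHC class I genes 0.061 with equal class weights. In mature DC-like cells the differences were 0.41 in maturation genes and 0.24 in NF-kB targets, but under the stricter filter they were 0.011 and -0.035, under the looser filter 0.024 and -0.022, and without doublet removal 0.10 and 0.061. In cDC1-like cells they were -0.038 (-0.19 to 0.095) and 0.30 (0.13 to 0.42), so maturation genes had no excess there. These are descriptions without a test of interaction, and the smaller libraries give the wider intervals. Those over all kept cells also follow the share of mature DC-like cells. It was 7.54% in Ad-Null, 8.32% in Ad-MEM40, 18.0% in Ad-mIFNB and 28.1% in Ad-COMBO.

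Within mature DC-like cells of Ad-MEM40, 6 of 22 NF-kB targets (median 0.39) and 4 of 20 maturation genes (0.34) were higher than in Ad-Null, and none of 28 type I interferon genes was. Cd70 (chromosome 17, 57145997 to 57149777) was at 97.9 CPM (91.2 to 105) against 20.6 (17.5 to 24.2), a ratio of 2.01, and Cxcl1 at 127 against 15.7 CPM (2.68). Il23a, the p19 subunit of interleukin 23, was at 2.17, Procr, the protein C receptor, at 2.02, Apoe at 1.30 and Ly6i at 1.19. The survival factor Bcl2l1 was at 1.06 and Tnfaip3, a feedback inhibitor of NF-kB, at 0.94. Macrophage markers had a median of 0.26 (1 of 12 higher, Apoe), and the lysozyme Lyz2 was at 373 against 174 CPM. Macrophage transcripts here were not told apart from free RNA or remaining doublets, and macrophage-like cells were 20.0% of Ad-MEM40 and 14.9% of Ad-Null. Type I interferon genes had a median of -0.11, a value that turned to 0.0046 under the stricter filter. Cd209a was at -1.23, Ccl17 at -1.08, and the C-type lectins Clec10a and Mgl2 at -0.88 and -0.73.

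Mature DC-like cells of Ad-mIFNB had 27 of 28 type I interferon genes higher (median 1.44), but maturation genes were level (0.02) and NF-kB targets nearly so (0.11). The latter turned to -0.033 with TMM scaling, which shifted every ratio of these cells by -0.15. Sct was at 125 against 8.17 CPM (3.30), Ly6c2 at 3.23, Slfn4, a Schlafen family gene, at 2.76, Lipg at 2.69 and Ifit3b at 2.53. Lta was at 2.50, Il6 at 1.53 and Tnf at 1.12. Cxcl9 was at 174 CPM (161 to 187) against 876 (855 to 897), a ratio of -2.30, beside Cd209a (-2.69), Lyz2 (-1.67) and Clec10a (-1.25).

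In mature DC-like cells of Ad-COMBO, 26 of 28 interferon genes (median 1.30) and 11 of 20 maturation genes (0.76) were higher, and 10 of 13 MHC class II genes were lower (-0.78). TMM scaling shifted every ratio of these cells by -0.11 and turned none of these medians. Sct was at 3.48, Dll4, a Notch ligand that steers T cell differentiation, at 51.5 CPM (41.9 to 62.7) against 1.07 (0.463 to 2.11), a ratio of 3.22, Plet1 at 3.11, Il27 at 2.77 and Plat, tissue plasminogen activator, at 2.71. Cd70 was at 2.14, Tnf at 2.16, Slamf1 at 1.86, Il15ra at 1.72 and Cd80, a ligand of CD28, at 1.17. Ciita, the master regulator of MHC-II, was at -1.24 and H2-DMb1 at -1.52. Macrophage markers were at -1.46 (11 of 12 lower) and cDC2 markers at -1.01, while cDC1 markers were at 0.82 and pDC markers at 1.17. Here too macrophage transcripts were not told apart from free RNA or remaining doublets, and macrophage-like cells were 9.28% of Ad-COMBO and 14.9% of Ad-Null. Cxcl9 was at -2.19, Clec4b1 at 1.56 CPM (0.322 to 4.56) against 66.0, from 3 UMIs, Lyz2 at -3.05, Ccr2 at -2.83, Cd209a at -2.60 and Emb at -2.54.

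The makeup of the mature DC-like class differed between libraries. Cluster 10, led by Lipg, Ccl5 and Fam89a, held 39.0%, 36.7%, 55.2% and 29.3% of it, and cluster 1 held 57.4%, 62.3%, 36.2% and 66.5%. At resolution 2 an unnamed cluster led by Lipg and Cd300e, with 5 macrophage markers high, took 67 of the 549 mature DC-like cells of Ad-Null, 118 of 1113 in Ad-MEM40, 49 of 326 in Ad-mIFNB and 1 of 188 in Ad-COMBO. At the same resolution a mature DC-like cluster led by Cd70, Procr and Plat, with Dll4 and Ccl22 among its leading genes, took 2, 138, 0 and 27 of them in the same order. Ratios over the whole class therefore do not separate such subsets from changes within all of its cells.

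The share of mature DC-like cells with a Cd70 UMI, after thinning each cell to 1000 UMIs, was 2.00% (1.00 to 3.56) in Ad-Null, 7.96% (6.43 to 9.71) in Ad-MEM40, 3.38% (1.70 to 5.98) in Ad-mIFNB and 8.02% (4.56 to 12.9) in Ad-COMBO. Cd70 was found in 0%, 0.0774%, 0% and 0% of macrophage-like cells, which should lack it. Il12b was found in 20.2%, 23.8%, 20.0% and 24.6% of mature DC-like cells and in 0.805%, 1.12%, 1.86% and 0% of macrophage-like cells. For Ccl22 the shares were 28.1%, 31.7%, 17.5% and 31.0%, against 0.704%, 2.63%, 0.621% and 0% in macrophage-like cells. Cxcl9 was found in 23.9%, 21.3%, 4.92% and 8.02%, against 1.56% and 1.39% of melanoma-like cells in Ad-Null and Ad-MEM40. Without thinning the shares were 14.8%, 19.4%, 13.8% and 28.2% for Cd70, 36.6%, 37.9%, 37.7% and 39.9% for Il12b and 50.5%, 43.1%, 17.5% and 26.1% for Cxcl9, while for Ccl22 they were 63.6%, 56.2%, 43.3% and 54.8%, so Ad-MEM40 and Ad-COMBO then lay below Ad-Null. Thinning left out 0, 7, 1 and 1 mature DC-like cells, whose median depths were 12330, 6718, 10637.5 and 7482 UMIs, against 14323, 8726, 12334 and 16030 in macrophage-like cells and 80958 and 48276.5 in melanoma-like cells of Ad-Null and Ad-MEM40.

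Within cDC1-like cells the interferon response of Ad-mIFNB and Ad-COMBO was the largest of the classes measured in both, and NF-kB targets were highest in Ad-COMBO. All 28 type I interferon genes were higher in both (medians 2.14 and 1.96), with Ifit3 at 4.22 and 3.45, against a median of 0.10 in Ad-MEM40. NF-kB targets had medians of 0.34, 0.34 and 0.87 in Ad-MEM40, Ad-mIFNB and Ad-COMBO, with Tnf at 2.31, Tnfaip3 at 1.89 and Nfkbia, the inhibitor IkB alpha, at 1.66 in Ad-COMBO. Maturation genes were at 0.15, 0.29 and 0.38, and the Ad-mIFNB value turned to -0.086 without doublet removal. Cd274, which encodes PD-L1, was 1.69 higher in Ad-COMBO, Tnfsf9, the ligand of 4-1BB, 1.36 and Cxcl10 2.68. Cell cycle genes were at -0.09, -0.66 and -0.95, with 14 of 16 lower in Ad-COMBO, where the survivin gene Birc5 was at -1.45. The makeup of the class differed, since cycling cluster 14 held 30.3%, 25.6%, 15.4% and 17.4% of cDC1-like cells in the 4 libraries and the shallow cluster 0 held 2.01%, 1.55%, 21.6% and 7.38%. Within cluster 14, Mki67 was at 0.045, -0.22 and 0.23 in Ad-MEM40, Ad-mIFNB and Ad-COMBO. Stress genes were at 0.28, 0.24 and 0.73, with the heat shock gene Hspa1a at 1.38 in Ad-COMBO.

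Macrophage-like cells carried the interferon response as well, with medians of 0.19, 1.42 and 1.29 in Ad-MEM40, Ad-mIFNB and Ad-COMBO, and 27 of 28 genes higher in the last, from 62 cells. Their maturation genes were at 0.16, 0.20 and -0.098, so these did not follow the order seen in mature DC-like cells. Phagocytosis genes of macrophage-like cells were at 0.11, 0.14 and 0.40. pDC-like cells of Ad-mIFNB had 21 of 24 interferon genes higher (1.52).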

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

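The tests of mature DC-like cells per cDC1-like cell, of Hist1h2ap in further classes and of free macrophage RNA were chosen only after the result was seen, and the depths and the Ccr7 and C1qa levels of the cells with both profiles were known before their other tests were written.

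The vector genes were also looked for in barcodes that the filter or the doublet call had left out, which no comparison above uses. For each of them the interval there lay wholly above that of Ad-Null in 1 library. Ifnb1 had 0 UMIs in the 269 left-out barcodes of Ad-mIFNB, and Cd40lg 1 UMI in those of Ad-COMBO. Ifnb1 was at 17.3 CPM (10.1 to 27.8) in the 286 left-out barcodes of Ad-COMBO, against 0.628 (0.426 to 0.891) in those of Ad-Null. All 17 UMIs lay in a single barcode called a doublet, so the value rests on 1 barcode, and in Ad-Null as well 1 left-out barcode held 17 UMIs. Cd40lg was at 0.846 CPM (0.605 to 1.15) in left-out barcodes of Ad-MEM40, against 0.0202 (0.000512 to 0.113) in Ad-Null. Of these 40 UMIs 34 lay in barcodes called doublets, 27 of them in 1. No explanation was tested for either.

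Mature DC-like cells made up more of the Ad-mIFNB and Ad-COMBO libraries than of Ad-Null. A loss of other cells that spared cDC1-like and mature DC-like cells alike would leave their ratio at its Ad-Null value. That value was 0.425 (0.384 to 0.470) mature DC-like cells per cDC1-like cell. The ratio was 1.26 (1.01 to 1.58) in Ad-COMBO and 1.02 (0.873 to 1.20) in Ad-mIFNB, which argues against such a loss. Depth does not account for the difference either, since among cells in a shared range of UMIs the share was 30.6% (25.6 to 35.9) in Ad-COMBO and 8.07% (7.25 to 8.95) in Ad-Null. A loss that spared mature DC-like cells but not cDC1-like cells, a difference in tissue digestion or sorting, and chance differences between tumors stay open, because each treatment had 1 library. So does the biological explanation that the viruses made more dendritic cells mature, which may hold but was not tested.

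Hist1h2ap was lower in the other 3 libraries than in Ad-Null. Fewer cycling cells of the same mix would leave its level unchanged within cycling cells. Yet it was at -2.03 (-2.12 to -1.94) in the cycling cDC1-like cluster of Ad-mIFNB, where Mki67 was at -0.22, and at -1.01 and -2.38 in that of Ad-MEM40 and Ad-COMBO. Hist1h2ap was itself a leading gene of that cluster, and the mix differed. At resolution 2 the cDC1-like cluster led by Hist1h1b and Hist1h2ap held 257, 329, 23 and 10 cells of Ad-Null, Ad-MEM40, Ad-mIFNB and Ad-COMBO. The cluster led by Cdc20 and Cenpf held 94, 128, 12 and 16, and that led by Hells and Ung 183, 256, 24 and 6. The ratios therefore argue only against fewer cycling cells of an unchanged mix. In mature DC-like cells of Ad-mIFNB Hist1h2ap was at -0.56 (-0.81 to -0.33), between the bounds set beforehand, although Mki67 was at 0.51 there. It was at -2.06 (-2.55 to -1.64) in those of Ad-COMBO, and in Ad-mIFNB at -2.40 (-2.79 to -2.05) in cDC2-like cells, whose extent depended on clustering, -3.85 (-4.07 to -3.66) in macrophage-like and -3.25 (-3.84 to -2.51, from 1 UMI) in pDC-like cells. These values differ more between classes than a library-wide difference in how this gene was counted would give by itself, but the share of cycling cells differed as well, so it cannot be told apart from a change in the cells.

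With fewer clustering features, a cluster that also formed at resolution 0.5 (417 cells in Ad-MEM40) carried both mature DC and macrophage transcripts, with 416 cells in Ad-MEM40 (3.11%), 33 in Ad-mIFNB (1.83%), 9 in Ad-Null (0.124%) and 5 in Ad-COMBO (0.749%), and 93.0% of those of Ad-MEM40 belong to cluster 9. Droplets with 2 cells would mix both profiles, and only 0.190% of 1578 genes, namely Saa3, Hbb-bs and Tppp3, lay 2-fold or more above both parents, with a median of 13283 UMIs against 6720.5 and 8778, but 4 erythroid markers were high as well, with Hbb-bs at 116 CPM against 0 and 0.299, which these 2 types alone do not supply. C1qa was 8.26 times its level in other mature DC-like cells, but such transcripts set this cluster apart, so the value does not decide on free RNA. Before doublet removal, chance pairs of the 2 types would give 0.485% in Ad-MEM40 and 0.0587% in Ad-mIFNB, below the shares seen among kept cells. Cells that stuck together before loading, free RNA or single cells with both programs may make up the rest, and the data here do not decide between them.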

How the results depend on the processing

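The set of main results was widened after the first run and never narrowed, and 3 of the 16 alternatives were chosen after seeing the data, namely the features without genes that differed within cDC1-like cells and the 2 that left out clusters. No paired analysis was possible because each group had a single library, so no result comes from a test.

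Of the main values under alternatives, 270 stayed within their counting interval, 233 moved beyond it and 1 turned. Only ratios and list medians whose main interval excluded 0 could count as turned. Shares could only stay or move, and their order against Ad-Null is given below. Type I interferon medians against Ad-Null ranged from 1.39 to 1.71 in Ad-mIFNB and from 1.37 to 1.79 in Ad-COMBO, and maturation medians of Ad-COMBO from 0.71 to 1.77. The maturation median of Ad-mIFNB ranged from 0.023, with equal class weights, to 0.77. Ad-COMBO stayed above Ad-mIFNB in maturation genes (0.67 to 0.94) and above the sum of the single ratios (0.35 to 0.62) in all kept cells. These values also follow the share of mature DC-like cells. Within mature DC-like cells the excess over that sum was 0.41, but it nearly vanished under the stricter and looser filters, as given above. In cDC1-like cells it was -0.038 (-0.19 to 0.095). Mature DC-like shares were higher than in Ad-Null under 8 of 8 alternatives in Ad-mIFNB and Ad-COMBO and under 7 in Ad-MEM40. Macrophage-like shares were higher in Ad-MEM40 and lower in the other two under 8 of 8, and cDC1-like shares were higher in Ad-COMBO under 8 of 8. The cDC2-like shares were lower in Ad-MEM40 and Ad-COMBO under 8 of 8 and in Ad-mIFNB under 7. Monocyte-like shares kept no order, with Ad-mIFNB higher than Ad-Null under 4 and lower under 4.

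Among the other values, 2259 stayed, 1663 moved and 62 turned. Of 90 named gene ratios only Lyz1 and Fn1 changed sign, and of 204 list medians 35 did under some alternative. Not all of these medians were small, and their values before and after are given below. These counts cover only values whose main counting interval excluded 0. Sign changes of values with an interval across 0 were not counted. Dropping the low-count filter moved no main result. Thinning the cells left too few members for the erythroid list, for T or NK cell markers in Ad-mIFNB and Ad-COMBO and for B cell and endothelial markers between these, the strict filter for the erythroid list, and leaving out other lineages for T or NK cell markers between Ad-COMBO and Ad-mIFNB. The cause was not tested for the changes below, except that scaling by TMM shifts every gene of a library alike and that unthinned cells show more genes because they hold more UMIs. Ad-COMBO had the fewest cells, 668 kept, 62 of them macrophage-like.

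Values below are the medians of lists against Ad-Null in all kept cells unless another comparison or class is named, and shares of kept cells, given for Ad-Null, Ad-MEM40, Ad-mIFNB and Ad-COMBO in this order where 4 stand without names. The single sum is the sum of the log2 ratios of Ad-MEM40 and Ad-mIFNB. Strict filtering kept cells with at least 1000 genes and at most 5% mitochondrial UMIs, and loose filtering those with at least 200 genes and at most 20%. In both, doublets were called by the expected share in Ad-Null and by the automatic threshold in Ad-MEM40, the reverse of the filter used above. Scaling without ribosomal genes also left out mitochondrial genes, and other lineages are melanoma-like, T or NK cell-like and fibroblast-like clusters. Shallow clusters are those of under 5000 median UMIs, all features include the response lists, and fewer features leave out genes that differed within cDC1-like cells.

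With strict filtering, Ad-MEM40 was at 0.11 (interferon), 0.23 (NF-kB) and 0.16 (maturation), and Ad-mIFNB was at 1.63 (interferon), 0.34 (NF-kB), 0.49 (maturation) and 0.42 (MHC class I). With strict filtering, Ad-COMBO was at 0.74 (NF-kB), 1.33 (maturation) and 0.63 (MHC class I), and Ad-COMBO against Ad-MEM40 was at 0.58 (MHC class I). With strict filtering, Ad-COMBO minus the single sum was at 0.62 (maturation). With strict filtering, over all kept cells, the sign turned for Ad-mIFNB phagocytosis from -0.020 to 0.045. With strict filtering, within cDC1-like cells, the sign turned for Ad-MEM40 inhibitory molecules from 0.058 to -0.029. With strict filtering, among mature DC-like cells, the sign turned for Ad-MEM40 interferon from -0.11 to 0.0046 and cell cycle from 0.19 to -0.24, Ad-mIFNB phagocytosis from 0.15 to -0.20 and Ad-COMBO minus the single sum interferon from 0.077 to -0.091, NF-kB from 0.24 to -0.035 and stress from -0.060 to 0.027. With strict filtering, cDC1-like shares were 15.9% in Ad-mIFNB, and cDC2-like shares were 25.3%, 18.8%, 21% and 14.6%. With strict filtering, mature DC-like shares were 6.70% in Ad-Null, 6.31% in Ad-MEM40 and 12.3% in Ad-mIFNB, and macrophage-like shares were 12.9% in Ad-Null and 21.8% in Ad-MEM40. With strict filtering, monocyte-like shares were 0.234%, 0.213%, 19.5% and 12.0%.

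With loose filtering, Ad-MEM40 was at 0.10 (interferon), 0.24 (NF-kB) and 0.24 (maturation), and Ad-mIFNB was at 1.62 (interferon), 0.33 (NF-kB), 0.52 (maturation) and 0.48 (MHC class I). With loose filtering, Ad-COMBO was at 1.67 (interferon) and 0.73 (NF-kB). With loose filtering, among mature DC-like cells, the sign turned for Ad-MEM40 chemokines from 0.17 to -0.018 and cell cycle from 0.19 to -0.065, Ad-mIFNB phagocytosis from 0.15 to -0.36 and Ad-COMBO minus the single sum NF-kB from 0.24 to -0.022, chemokines from -0.79 to 0.086 and stress from -0.060 to 0.012. With loose filtering, cDC1-like shares were 15.8% in Ad-Null, 19.9% in Ad-mIFNB and 28.4% in Ad-COMBO, and cDC2-like shares were 18.0%, 14.4%, 7.43% and 0.719%. With loose filtering, mature DC-like shares were 6.35%, 7.18%, 14.8% and 24.3%, and macrophage-like shares were 11.4% in Ad-Null, 15.2% in Ad-MEM40 and 6.71% in Ad-COMBO. With loose filtering, monocyte-like shares were 14.7%, 16.4%, 28.6% and 17.9%.

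With doublets kept, Ad-MEM40 was at 0.24 (NF-kB), 0.22 (maturation) and 0.021 (MHC class I), and Ad-mIFNB was at 1.62 (interferon), 0.32 (NF-kB) and 0.49 (maturation). With doublets kept, Ad-COMBO was at 1.66 (interferon) and 0.73 (NF-kB), and Ad-COMBO minus the single sum was at 0.29 (NF-kB) and 0.50 (maturation). With doublets kept, within cDC1-like cells, the sign turned for Ad-MEM40 inhibitory molecules from 0.058 to -0.055, Ad-mIFNB maturation from 0.29 to -0.086 and inhibitory molecules from 0.20 to -0.047 and Ad-COMBO chemokines from 0.17 to -0.19. With doublets kept, among mature DC-like cells, the sign turned for Ad-MEM40 cell cycle from 0.19 to -0.14, Ad-mIFNB cell cycle from 0.44 to -0.22 and phagocytosis from 0.15 to -0.20 and Ad-COMBO minus the single sum stress from -0.060 to 0.00067. With doublets kept, cDC1-like shares were 16.8% in Ad-Null and 13.3% in Ad-MEM40, and cDC2-like shares were 26.7% in Ad-Null and 19.3% in Ad-MEM40. With doublets kept, mature DC-like shares were 6.69% in Ad-Null, 7.03% in Ad-MEM40 and 14.7% in Ad-mIFNB, and pDC-like shares were 1.83% in Ad-MEM40. With doublets kept, macrophage-like shares were 18.5%, 26.5%, 14.3% and 14.3%, and monocyte-like shares were 6.11% in Ad-Null, 9.59% in Ad-MEM40 and 1.60% in Ad-mIFNB. With doublets kept, melanoma-like shares were 1.99% in Ad-MEM40.

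With TMM scaling, Ad-MEM40 was at 0.089 (interferon), 0.24 (NF-kB) and 0.0031 (MHC class I), and Ad-COMBO was at 1.64 (interferon), 0.73 (NF-kB) and 0.60 (MHC class I). With TMM scaling, Ad-COMBO against Ad-mIFNB was at 0.025 (interferon), 0.37 (NF-kB) and 0.14 (MHC class I), and Ad-COMBO minus the single sum was at 0.37 (maturation). With TMM scaling, among mature DC-like cells, the sign turned for Ad-mIFNB NF-kB from 0.11 to -0.033 and MHC class I from 0.13 to -0.0083.

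Without ribosomal genes, Ad-MEM40 was at 0.091 (interferon), 0.24 (NF-kB) and 0.0041 (MHC class I), and Ad-mIFNB was at 1.62 (interferon), 0.35 (NF-kB) and 0.40 (MHC class I). Without ribosomal genes, Ad-COMBO was at 1.64 (interferon), 0.74 (NF-kB) and 0.60 (MHC class I).

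With 1 CPM added, Ad-MEM40 was at 0.46 (maturation), and Ad-mIFNB was at 1.71 (interferon) and 0.77 (maturation). With 1 CPM added, Ad-COMBO was at 1.74 (interferon) and 1.62 (maturation), and Ad-COMBO against Ad-MEM40 was at 1.61 (interferon) and 1.27 (maturation).

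With equal weights, Ad-MEM40 was at 0.16 (interferon), 0.18 (NF-kB) and 0.095 (MHC class I), and Ad-mIFNB was at 1.39 (interferon), 0.11 (NF-kB), 0.023 (maturation) and 0.22 (MHC class I). With equal weights, Ad-COMBO was at 1.37 (interferon), 0.57 (NF-kB), 0.71 (maturation) and 0.44 (MHC class I). With equal weights, Ad-COMBO against Ad-MEM40 was at 1.35 (interferon), 0.32 (NF-kB), 0.40 (maturation) and 0.38 (MHC class I), and Ad-COMBO against Ad-mIFNB was at 0.11 (MHC class I). With equal weights, Ad-COMBO minus the single sum was at 0.20 (NF-kB), 0.35 (maturation) and 0.061 (MHC class I). With equal weights, over all kept cells, the sign turned for Ad-MEM40 cDC2 markers from -0.23 to 0.043, T or NK cell markers from 0.057 to -0.0024, melanoma markers from 0.62 to -0.084, endothelial markers from 0.13 to -0.0088, MHC class II from -0.20 to 0.032 and hypoxia from 0.13 to -0.11, Ad-mIFNB mature DC markers from 0.62 to -0.15, endothelial markers from 0.17 to -0.016, hypoxia from -0.20 to 0.067, phagocytosis from -0.020 to 0.094 and Lyz1 from -1.72 to 0.87 and Ad-COMBO T or NK cell markers from 0.31 to -0.0094 and Fn1 from -1.77 to 1.31. With equal weights, also over all kept cells, the sign turned for Ad-COMBO against Ad-MEM40 macrophage markers from -0.60 to 0.068, erythroid markers from -0.51 to 0.00073, MHC class II from 0.049 to -0.20, hypoxia from -0.53 to 0.087 and phagocytosis from -0.18 to 0.33, Ad-COMBO against Ad-mIFNB neutrophil markers from 0.16 to -0.34, melanoma markers from -0.28 to 0.0065 and interferon from 0.086 to -0.051 and Ad-COMBO minus the single sum cDC2 markers from -0.27 to 0.023, cytokines from 0.12 to -0.054 and phagocytosis from -0.12 to 0.12.

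With thinned cells, Ad-MEM40 was at 0.080 (interferon) and 0.36 (maturation), and Ad-mIFNB was at 0.49 (MHC class I). With thinned cells, Ad-COMBO was at 1.79 (interferon), 0.85 (NF-kB) and 1.77 (maturation). With thinned cells, Ad-COMBO against Ad-MEM40 was at 1.61 (interferon), 0.67 (NF-kB), 1.26 (maturation) and 0.56 (MHC class I). With thinned cells, Ad-COMBO against Ad-mIFNB was at 0.027 (interferon), 0.52 (NF-kB), 0.94 (maturation) and 0.12 (MHC class I). With thinned cells, Ad-COMBO minus the single sum was at -0.053 (interferon), 0.38 (NF-kB) and 0.074 (MHC class I). With thinned cells, over all kept cells, the sign turned for Ad-MEM40 endothelial markers from 0.13 to -0.13, Ad-COMBO macrophage markers from 0.20 to -0.31 and phagocytosis from 0.19 to -0.011 and Ad-COMBO against Ad-MEM40 MHC class II from 0.049 to -0.10. With thinned cells, also over all kept cells, the sign turned for Ad-COMBO minus the single sum B cell markers from -0.079 to 0.16. With thinned cells, within cDC1-like cells, the sign turned for Ad-MEM40 MHC class I from 0.027 to -0.017 and cytokines from 0.13 to -0.091, Ad-mIFNB cytokines from 0.29 to -0.20 and Ad-COMBO chemokines from 0.17 to -0.19. With thinned cells, among mature DC-like cells, the sign turned for Ad-mIFNB cell cycle from 0.44 to -0.34 and phagocytosis from 0.15 to -0.029 and Ad-COMBO minus the single sum stress from -0.060 to 0.050.

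At resolution 0.5, cDC2-like shares were 32.9%, 23.1%, 35.2% and 18.0%, and mature DC-like shares were 7.75% in Ad-MEM40. At resolution 0.5, macrophage-like shares were 28.5%, 39.7%, 17.6% and 18.0%, and monocyte-like shares were 0.261% in Ad-Null, 0.904% in Ad-MEM40 and 0.111% in Ad-mIFNB. The macrophage-like class there included the cluster led by Retnla, Lyz1 and Fn1 and the one led by histone genes.

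At resolution 2, cDC2-like shares were 20.3% in Ad-Null, 15.3% in Ad-MEM40 and 6.09% in Ad-mIFNB, and mature DC-like shares were 6.62% in Ad-Null, 7.42% in Ad-MEM40 and 15% in Ad-mIFNB. At resolution 2, macrophage-like shares were 17.7%, 26.9%, 11.3% and 13.6%, and monocyte-like shares were 0.357% in Ad-Null, 0.904% in Ad-MEM40 and 0.111% in Ad-mIFNB.

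With all features, cDC2-like shares were 28.1%, 18.8%, 8.41% and 2.10%, and mature DC-like shares were 6.24% in Ad-Null, 7.16% in Ad-MEM40 and 14.1% in Ad-mIFNB. With all features, macrophage-like shares were 17.6%, 26.3%, 13.9% and 14.8%, and monocyte-like shares were 7.26% in Ad-MEM40, 33.6% in Ad-mIFNB and 20.4% in Ad-COMBO.

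With fewer features, cDC2-like shares were 23% in Ad-MEM40, 22.2% in Ad-mIFNB and 8.83% in Ad-COMBO, and mature DC-like shares were 6.83% in Ad-Null, 7.53% in Ad-MEM40 and 15.1% in Ad-mIFNB. With fewer features, macrophage-like shares were 18.1%, 26.2%, 13.8% and 15.3%, and monocyte-like shares were 5.71%, 5.76%, 14.8% and 9.13%.

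Without other lineages, Ad-MEM40 was at 0.072 (MHC class I), and Ad-COMBO was at 0.77 (NF-kB) and 0.64 (MHC class I). Without other lineages, Ad-COMBO against Ad-MEM40 was at 1.48 (interferon), 0.45 (NF-kB) and 0.56 (MHC class I). Without other lineages, Ad-COMBO minus the single sum was at -0.13 (interferon), 0.21 (NF-kB) and 0.36 (maturation). Without other lineages, over all kept cells, the sign turned for Ad-mIFNB phagocytosis from -0.020 to 0.0037, Ad-COMBO against Ad-MEM40 MHC class II from 0.049 to -0.041 and Ad-COMBO against Ad-mIFNB melanoma markers from -0.28 to 0.42.

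Without shallow clusters, Ad-mIFNB was at 1.69 (interferon). Without shallow clusters, cDC1-like shares were 19.6% in Ad-Null, 15.9% in Ad-MEM40 and 15.9% in Ad-mIFNB, and cDC2-like shares were 35.4% in Ad-Null, 24.8% in Ad-MEM40 and 13.3% in Ad-mIFNB. Without shallow clusters, mature DC-like shares were 8.20% in Ad-Null and 9.20% in Ad-MEM40, and macrophage-like shares were 13.1% in Ad-Null, 17.6% in Ad-MEM40 and 7.50% in Ad-mIFNB. Without shallow clusters, monocyte-like shares were 8.30% in Ad-Null and 7.21% in Ad-MEM40.

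Without thinning, Il12b was found in 36.6%, 37.9%, 37.7% and 39.9% of mature DC-like cells. Without thinning, Cxcl9 was found in 50.5%, 43.1%, 17.5% and 26.1% of mature DC-like cells. Without thinning, Ccl22 was found in 63.6%, 56.2%, 43.3% and 54.8% of mature DC-like cells. Without thinning, Cd70 was found in 14.8%, 19.4%, 13.8% and 28.2% of mature DC-like cells.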

Other observations

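No test in this part was planned or run, and the clusters and genes below were picked after their values were seen.

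The few cells of Ad-Null in cluster 6 carried nearly as much interferon response as those of the interferon beta libraries. Against the 52 Ad-Null cells, type I interferon genes had a median of 0.16 in the 463 cells of Ad-mIFNB (3 of 28 higher) and 0.25 in the 120 of Ad-COMBO (9 of 28 higher), and cells enter this cluster because they resemble each other. Other genes differed more. Ly6c2 was at 1.64 in Ad-mIFNB, and Il4i1, an immune-regulatory enzyme, at 1.59 and 1.76 in Ad-mIFNB and Ad-COMBO. H2-Q7, a nonclassical MHC class I gene, was at 1.31 and 1.40. Cxcl9 was at -2.83 and -1.53, and interferon gamma associated genes had a median of -0.58 in Ad-mIFNB (8 of 17 lower) but 0.076 in Ad-COMBO.

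Mature DC-like cells of the interferon beta libraries also carried more pDC marker transcripts, with medians of 0.99 in Ad-mIFNB (5 of 9 higher) and 1.17 in Ad-COMBO (6 of 9 higher), against 0.067 in Ad-MEM40. Their cytokine genes had medians of 0.40, 0.64 and 0.56 in Ad-MEM40, Ad-mIFNB and Ad-COMBO. In macrophage-like cells of Ad-COMBO, cytokines were at 0.44 (7 of 17 higher) and MHC class I genes at 0.38 (8 of 19 higher).

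Cluster 9, led by Saa3, Cd5l and Cbr2, held 1091 cells in Ad-MEM40 and 125 in Ad-Null, and 14 of 17 interferon gamma associated genes were higher in the Ad-MEM40 cells (0.92), with Iigp1 at 2.05 and Gbp2 at 1.70. Of these Ad-MEM40 cells 387 carried both mature DC and macrophage transcripts, against at most 9 of the Ad-Null cells, so unlike cells are compared. Cluster 21, led by Inhba, Nos2 and Gm15056, held 4.64% of Ad-MEM40 cells and at most 1.05% of any other library. In cluster 11, led by Retnla, Lyz1 and Fn1, Ccl5 was at 1.66 and Iigp1 at 1.43 in Ad-MEM40.

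Ribosomal protein genes took 17.9%, 15.7%, 15.6% and 14.0% of the UMIs of kept cells in Ad-Null, Ad-MEM40, Ad-mIFNB and Ad-COMBO, and mitochondrial genes 2.59%, 2.57%, 1.97% and 2.35%.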
